A study of Rattus norvegicus with 8 samples.

How the data were processed

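Gene expression was measured in the livers of male Sprague-Dawley rats of 180 to 200 g that received dexamethasone (1.5 mg/kg into muscle), AICAR (0.7 g/kg into the peritoneum), both or saline, with tissue taken 8 h after the injection, per the labels. Total RNA was purified on silica columns, turned into biotin-labelled cRNA with the array maker's labelling kit and hybridised to an Affymetrix rat expression array, per the labels' protocols. The 4 groups held 2 arrays each. The labels do not say that the 2 arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

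The deposited table holds 1 value per probe set and array, made by the authors with RMA in the affy package, per the submitters' processing notes. Versions were not given in the sources used here. RMA corrects the background, sets the arrays to 1 common distribution of values and summarises the probes of a probe set on the log2 scale. The base of the logarithm is not stated in words, and the deposited values were read as log2 because they run over the range that RMA writes. Array medians lay between 5.22 and 5.27. RMA gives no detection call, and it compresses fold changes of dim probe sets, so a fold change towards a low level tends to be understated. For 31 called results of named genes a compared group had a mean below 3.84, the lowest lower quartile of the arrays, and the size of these changes is uncertain.

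The table held 31099 probe sets, of which 57 array controls were kept out of all tests, leaving 31042. Names came from the platform annotation, checked by gene ID against a table of rat genes from the GRCr8 assembly that was used for names alone. Of the tested probe sets, 20826 carried 1 gene symbol, 436 carried several and 9780 carried none here. A gene was named only from a probe set with 1 symbol, which gave 14216 genes, and a gene with several probe sets was represented by the one with the highest mean over all 8 arrays. No coordinates are given, because no genome build was used in making the values.

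Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group fitted over all 8 arrays, empirical Bayes moderation (4 residual and 4.58 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 31042 probe sets. A probe set was called at an adjusted p under 0.05. With 2 arrays against 2, an exact permutation test of a single gene cannot go below a two-sided p of 0.333, so no test of that kind was made. The comparisons were each treatment against vehicle, the combination against each single treatment, and the interaction, which is the dexamethasone effect with AICAR minus that without. The code was tested on simulated data of 31042 probe sets for the comparison of dexamethasone with vehicle. It recovered 50% of changes of 0.5 on the log2 scale, 86% of changes of 1 and 100% of changes of 2 and of 3, with 6 false calls among 174. At each of these sizes 50 probe sets were changed, a far smaller share than was called in the data, so the rates need not hold there.

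A collection of 33 gene lists (metabolic pathways, hormone and stress responses, and markers of the cell types of liver) was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Of 639 symbols on the lists, 566 matched a gene here. A gene could be on several lists, so the results of different lists are not independent. Camera was also run with an estimated correlation. With it, the call of 1 list held in the comparison of dexamethasone with vehicle, cell proliferation, and none held in the other comparisons. The test fry, which asks whether the genes of a list move 1 way on balance without setting them against other genes, called between 20 and 26 lists per comparison. For every list that camera called, the median, the mean and the test had the same sign.

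The groups, the tests, the 33 gene lists, the rule for naming genes and most alternatives were set before the data were examined. The alternatives for the correlation of the AICAR effect and the 2 rescalings (cyclic loess, centring) of the gene lists were added after. The rule named the 8 largest rises and 8 largest falls per comparison among called genes, up to 4 called members with the smallest p from each list that was called or had 3 or more called members, and a panel of glucocorticoid-responsive and metabolic genes in every comparison, called or not. The text gives 10 panel genes; panel genes with no probe set of their own in the annotation are not reported here. Alternatives were a filter on dim probe sets, a trended and robust prior, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, cyclic loess between arrays, centring on the brighter probe sets, gene means over probe sets, and the removal of each array in turn. A set of 6 further lists was added after the data were seen and is used in the closing part alone.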

Results

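Liver transcripts were profiled in rats 8 h after dexamethasone, a synthetic glucocorticoid, after AICAR, a nucleoside that activates the energy-sensing kinase AMPK, after both agents, and after saline vehicle. The question behind the design was whether AMPK alters the metabolic effects of glucocorticoids, with p38 MAPK and the glucocorticoid receptor as the proposed route. Each of the 4 groups held 2 arrays, and this number limits the precision of every value. The 2 arrays of a group correlated at r = 0.997 to 0.998 across probe sets, against 0.979 to 0.993 between groups, and the median SD within groups was 0.0952 on the log2 scale. Values after ± are standard errors of log2 fold changes from limma (n = 2 arrays per group).

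Control probe sets for actin and GAPDH gave a measure of RNA quality in each group. The difference between the 3′ and 5′ ends of the actin control was 2.23 ± 0.04 (SD, n = 2) in vehicle, 2.04 ± 0.01 after dexamethasone, 1.82 ± 0.03 after AICAR and 1.80 ± 0.04 after both, on the log2 scale. For the GAPDH control it was 0.61 in vehicle, 0.42 after dexamethasone, 0.39 after AICAR and 0.33 after both. Both differences were largest in vehicle, and both were smaller after the combination than after dexamethasone alone. RNA quality therefore cannot be told apart from treatment in comparisons with vehicle. The same holds for the combination against dexamethasone and for the interaction. This matters most for small changes. The 5S ribosomal RNA control read 6.29 ± 0.10 in vehicle, 6.59 ± 0.05 after dexamethasone, 6.71 ± 0.05 after AICAR and 7.51 ± 0.06 after both.

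The first comparison asked what dexamethasone did alone. Transcripts known to respond to glucocorticoids were higher than in vehicle. Tsc22d3, which encodes the leucine zipper protein GILZ, rose by 2.05 ± 0.10 on the log2 scale (4.13-fold, adjusted p = 3.18e-06). The receptor co-chaperone gene Fkbp5 rose by 1.40 ± 0.10, the IGF-binding protein gene Igfbp1 by 1.45 ± 0.07 and the clock gene Per1 by 0.94 ± 0.12. Smaller rises were seen for Tat, which encodes tyrosine aminotransferase (0.82 ± 0.07, adjusted p = 6.84e-05), for the coactivator gene Ppargc1a (0.57 ± 0.10) and for Pck1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase (0.45 ± 0.07, adjusted p = 0.00246). Sgk1, a kinase gene often induced by glucocorticoids, fell by 1.49 ± 0.07.

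The largest rises after dexamethasone were in the carboxylesterase gene Ces2c (6.10 ± 0.14, or 68.6-fold), the sugar transporter gene Slc5a11 (4.51 ± 0.15), Zfp354a (4.29 ± 0.07), the protease inhibitor gene A2m (4.22 ± 0.09) and the retinol-binding protein gene Rbp7 (4.10 ± 0.20). Isg15, an interferon-stimulated gene, rose by 3.50 ± 0.09. The largest fall was in Serpina7, which encodes thyroxine-binding globulin (-4.34 ± 0.13, or 20.2-fold lower). Other large falls were in the methyltransferase gene Inmt (-3.98 ± 0.13) and the cell cycle genes Cdkn3 (-3.81 ± 0.16), Ect2 (-3.35 ± 0.15), Cdk1 (-3.20 ± 0.16) and Ccna2 (-3.19 ± 0.14). Slc5a11 in vehicle (3.03) and Ect2 (3.41) and Ccna2 (2.73) after dexamethasone had means below 3.84, so the size of these changes is uncertain. In all, 5726 of 31042 probe sets were called, 2692 higher and 3034 lower, and 605 of them changed at least 2-fold.

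Among metabolic lists, 20 of 26 glucocorticoid receptor target genes rose and 3 fell (21 and 3 when adjusted over the list alone), with a median of 0.85. The metallothionein gene Mt2A rose by 3.27 ± 0.07, the phosphatidate phosphatase gene Lpin1 by 2.43 ± 0.09 and Sds, which encodes serine dehydratase, by 2.16 ± 0.07. Camera called the list at the preset correlation (list adjusted p = 9.97e-13, and adjusted p = 0.103 with an estimated correlation). Of 24 genes of amino acid catabolism and the urea cycle, 17 rose and 3 fell (17 and 3 when adjusted over the list alone; adjusted p = 2.63e-07, and adjusted p = 0.154 with an estimated correlation). Prodh rose by 1.10 ± 0.08 and Bckdhb by 1.08 ± 0.07, while the kynurenine enzyme gene Kmo fell by 1.35 ± 0.08. Of 18 gluconeogenic and glucose output genes, 11 rose and 1 fell (12 and 1 when adjusted over the list alone), among them the transaminase genes Gpt (1.97 ± 0.07) and Got1 (1.32 ± 0.07) and the glucose 6-phosphate transporter gene Slc37a4 (1.25 ± 0.07). That list gave adjusted p = 8.59e-07, and adjusted p = 0.154 with an estimated correlation. Glycolysis genes rose in 7 of 16 cases with no fall (7 and 0 when adjusted over the list alone), led by Pfkfb1 (1.99 ± 0.09; adjusted p = 1.88e-04 for the list, and adjusted p = 0.155 with an estimated correlation).

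Genes of protein synthesis and respiration were also higher. Of 18 cytosolic ribosomal protein genes 11 rose and none fell (14 and 0 when adjusted over the list alone), with list adjusted p = 2.03e-07 and adjusted p = 0.237 with an estimated correlation. Rpl4 changed by 0.55 ± 0.07 and Rpl3 by 0.43 ± 0.07. Of 25 respiratory chain genes 16 rose and 1 fell (18 and 1 when adjusted over the list alone), with list adjusted p = 2.63e-07 and adjusted p = 0.23 with an estimated correlation. Cyc1 changed by 0.74 ± 0.08 and Ndufs1 by 0.64 ± 0.09. Periportal hepatocyte markers rose in 7 of 11 cases and fell in 1 (7 and 2 when adjusted over the list alone), with Ass1, a urea cycle gene, at 0.90 ± 0.07 (adjusted p = 5.38e-04 for the list, and adjusted p = 0.154 with an estimated correlation). In the list of amino acid response and endoplasmic reticulum stress genes 7 of 24 rose and 3 fell (9 and 3 when adjusted over the list alone). Herpud1 changed by 1.34 ± 0.10 and Hyou1 by -0.83 ± 0.07 (list adjusted p = 0.0177, and adjusted p = 0.242 with an estimated correlation).

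Proliferation genes were lower after dexamethasone: 18 of 23 fell and none rose (21 and 0 when adjusted over the list alone), with a median of -0.63. Ccnb2 fell by 2.58 ± 0.13, Ccnd1 by 2.43 ± 0.09 and Ube2c by 1.99 ± 0.09, and this list kept its call either way (list adjusted p = 2.13e-11, and adjusted p = 0.0471 with an estimated correlation). Cholesterol synthesis and uptake genes fell in 15 of 21 cases and rose in 2 (17 and 2 when adjusted over the list alone). Cyp51 changed by -1.36 ± 0.07 and Msmo1 by -1.26 ± 0.07 (list adjusted p = 1.09e-06, and adjusted p = 0.222 with an estimated correlation). Of 17 antioxidant genes controlled by NRF2, 12 fell and 2 rose (14 and 2 when adjusted over the list alone), with list adjusted p = 5.39e-05 and adjusted p = 0.154 with an estimated correlation. Ephx1 changed by -2.03 ± 0.07 and Gclc by -0.91 ± 0.08.

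Markers of several other cell types of liver fell in the same arrays. Of 11 Kupffer cell and macrophage markers 9 fell and 1, Lyz2, rose (10 and 1 when adjusted over the list alone). Cd5l changed by -1.87 ± 0.07, Adgre1 by -1.56 ± 0.14 and Cd14 by -1.25 ± 0.07 (list adjusted p = 7.73e-06, and adjusted p = 0.154 with an estimated correlation). Of 15 lymphocyte markers 7 fell (9 when adjusted over the list alone), among them the B cell gene Ms4a1 (-1.23 ± 0.13), with list adjusted p = 4.27e-04 and adjusted p = 0.155 with an estimated correlation. Of 11 sinusoidal endothelial markers 6 fell (8 when adjusted over the list alone), and the scavenger receptor gene Stab2 changed by -1.04 ± 0.08 (list adjusted p = 0.00318, and adjusted p = 0.154 with an estimated correlation). Of 6 erythroid markers 3 fell (5 when adjusted over the list alone). Ahsp changed by -1.05 ± 0.08 and Alas2 by -0.62 ± 0.08; the third, Epb42 (-0.64 ± 0.16), lost its call without either vehicle array (adjusted p = 0.0807 and 0.0906). The erythroid list gave adjusted p = 0.00517, and adjusted p = 0.154 with an estimated correlation.

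Nr3c1, which encodes the glucocorticoid receptor, was only marginally lower after dexamethasone (-0.31 ± 0.09, adjusted p = 0.043). Its call ended under cyclic loess (adjusted p = 0.0598), under centring (adjusted p = 0.0613), when its probe sets were averaged (-0.07, adjusted p = 0.525), and without any 1 array other than dexamethasone replicate 1 (adjusted p from 0.0618 to 0.197). The rise of Srebf1, a lipogenic transcription factor gene (0.33 ± 0.08, adjusted p = 0.0273), ended without vehicle replicate 2 (adjusted p = 0.152) or dexamethasone replicate 2 (adjusted p = 0.126). Without vehicle replicate 2, 3738 probe sets were called in place of 5726.

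The next comparison asked what AICAR did alone. Lcn2, which encodes the iron-sequestering protein lipocalin 2, rose by 5.88 ± 0.11 (58.8-fold, adjusted p = 1.46e-07). Wfdc21 rose by 3.47 ± 0.08, the lipopolysaccharide-binding protein gene Lbp by 2.88 ± 0.07, the sulfide oxidation gene Sqor by 2.65 ± 0.15, Timp1 by 2.05 ± 0.08 and the phospholipase gene Pla2g2a by 1.96 ± 0.09. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.11 ± 0.07 and the quinone reductase gene Nqo1 by 2.06 ± 0.07. Among the largest falls were those of the aminopeptidase gene Dnpep (-2.77 ± 0.09), the hepcidin gene Hamp (-2.17 ± 0.09), A2m (-1.89 ± 0.09), the hepatocyte transcription factor gene Onecut1 (-1.84 ± 0.09), Serpina7 (-1.82 ± 0.13) and Lox (-1.74 ± 0.08).

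Sterol genes moved as a group after AICAR. Of 21 cholesterol synthesis and uptake genes 17 rose and none fell (20 and 1 when adjusted over the list alone), with a median of 0.49. Acat2 rose by 0.92 ± 0.08, Fdps by 0.86 ± 0.07 and Sqle by 0.71 ± 0.07 (adjusted p = 1.79e-13 for the list, and adjusted p = 0.28 with an estimated correlation). Fatty acid and triglyceride synthesis genes rose in 8 of 21 cases with no fall (9 and 1 when adjusted over the list alone), with list adjusted p = 3.13e-04 and adjusted p = 0.28 with an estimated correlation. Thrsp changed by 1.42 ± 0.08 and the acetyl-CoA carboxylase gene Acaca by 0.67 ± 0.07. Of 21 fatty acid oxidation and ketogenesis genes 6 fell and none rose (8 and 0 when adjusted over the list alone), including Ehhadh (-1.11 ± 0.10) and Decr1 (-0.58 ± 0.07). That list gave adjusted p = 0.0331, adjusted p = 0.579 with an estimated correlation, and no call under cyclic loess.

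Acute phase proteins rose in 8 of 19 cases and fell in 2 (9 and 3 when adjusted over the list alone; adjusted p = 4.9e-04, and adjusted p = 0.28 with an estimated correlation). Stellate cell and fibroblast markers rose in 7 of 13 cases with no fall (7 and 2 when adjusted over the list alone), led by the matrix genes Lum (1.61 ± 0.08), Col1a1 (1.37 ± 0.08) and Dcn (0.95 ± 0.08), with list adjusted p = 0.00109 and adjusted p = 0.28 with an estimated correlation. Stress genes of the endoplasmic reticulum and amino acid response rose in 6 of 24 cases and fell in 1 (9 and 1 when adjusted over the list alone), including Hyou1 (0.84 ± 0.07; adjusted p = 0.00109 for the list, and adjusted p = 0.28 with an estimated correlation). Of 25 cytokine, chemokine and NF-kB target genes 6 rose and 3 fell (9 and 3 when adjusted over the list alone). Cxcl9 changed by 1.10 ± 0.09 and Cxcl1 by -1.08 ± 0.13 (list adjusted p = 0.021, and adjusted p = 0.455 with an estimated correlation). Periportal markers fell in 4 of 11 cases (5 when adjusted over the list alone). Sds changed by -1.26 ± 0.07 and the glutaminase gene Gls2 by -0.72 ± 0.07 (list adjusted p = 0.00427, and adjusted p = 0.28 with an estimated correlation). Of 18 ribosomal protein genes 3 rose (3 when adjusted over the list alone), led by Rplp0 (0.46 ± 0.07; adjusted p = 0.0137 for the list, and adjusted p = 0.579 with an estimated correlation). Macrophage markers rose in 4 of 11 cases and fell in 1 (6 and 2 when adjusted over the list alone), with a median of 0.27 and no call for the list (adjusted p = 0.155).

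AICAR alone did not move the glucocorticoid receptor targets 1 way: 8 of 26 rose and 6 fell (11 and 8 when adjusted over the list alone; adjusted p = 0.484). Igfbp1 rose by 1.03 ± 0.07 and Sgk1 fell by 1.07 ± 0.07. Tsc22d3 (0.26 ± 0.10, adjusted p = 0.123), Fkbp5 (-0.23 ± 0.10, adjusted p = 0.156), Pck1 (0.15 ± 0.07, adjusted p = 0.211), Ppargc1a (0.14 ± 0.10, adjusted p = 0.379) and Srebf1 (-0.06 ± 0.08, adjusted p = 0.709) did not pass, and the other probe set of Srebf1 was called higher. Tat (-0.36 ± 0.07) passed with all arrays but not without any 1 of the vehicle or AICAR arrays (adjusted p from 0.0565 to 0.0703). Nr3c1 (-0.45 ± 0.09) lost its call without vehicle replicate 1 (adjusted p = 0.0802) or AICAR replicate 1 (adjusted p = 0.0885) and when its probe sets were averaged (adjusted p = 0.0975). Per1 (0.43 ± 0.12) lost its call without any 1 array other than AICAR replicate 1 (adjusted p from 0.0595 to 0.195).

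Of 31042 probe sets, 4011 were called after AICAR alone, 1692 higher and 2319 lower, and 169 changed at least 2-fold. This balance depended on the scaling of the arrays: 42.2% of called probe sets were higher as deposited, 47.8% with cyclic loess and 51.5% with centring. The count fell to 1713 and 1920 without vehicle replicate 1 and 2, and to 1447 and 1989 without AICAR replicate 1 and 2. Of 21 genes on the list of AMPK, p38 MAPK and the glucocorticoid receptor, which also holds regulators linked to them such as Stk11, Crtc2, Mtor, Tsc2, Ncoa1 and Ncoa2, none rose and 5 fell (0 and 6 when adjusted over the list alone; adjusted p = 0.343 for the list), with the AMPK subunit gene Prkag2 at -0.60 ± 0.08.

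**Figure D1:**
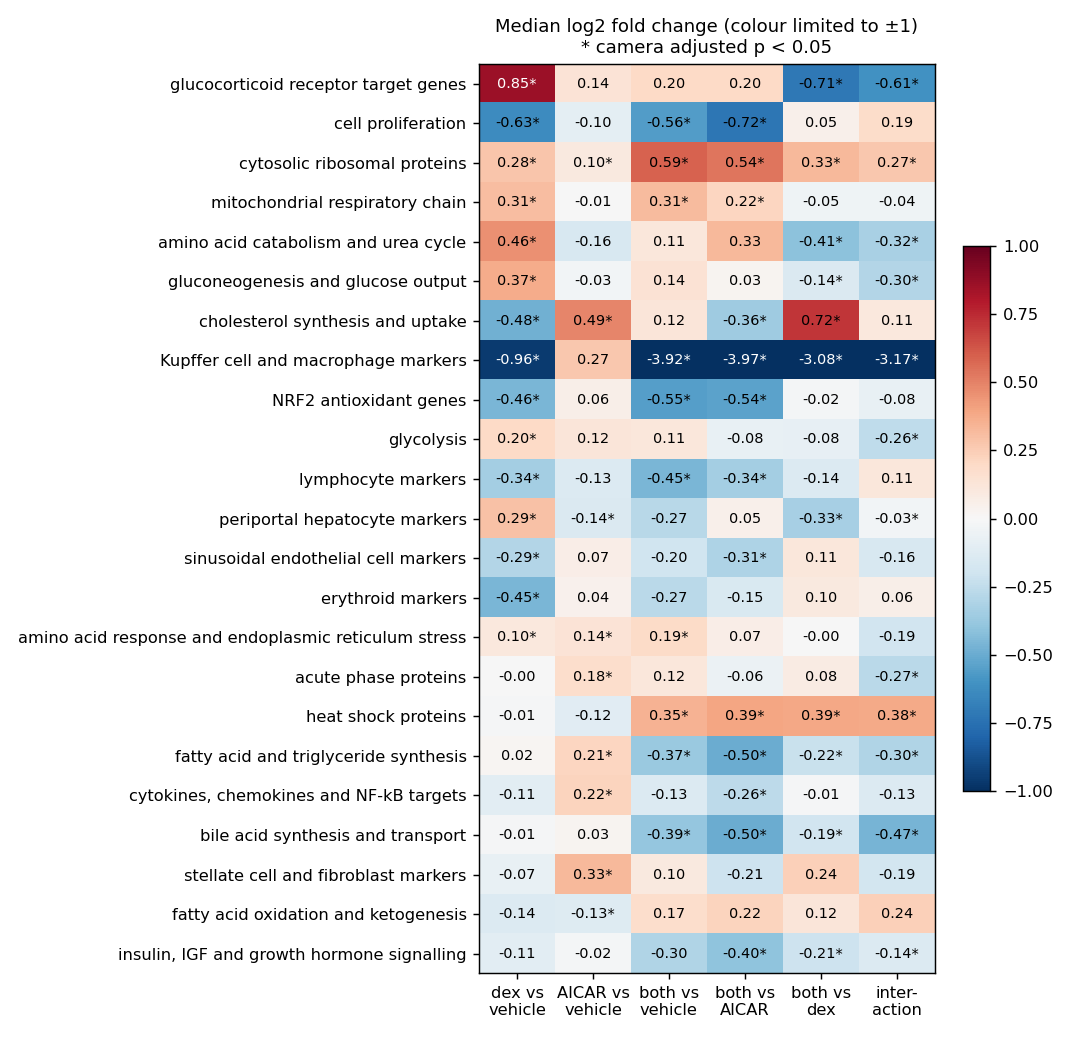
Median log2 fold change of each gene list (vertical axis) in each of the 6 comparisons (horizontal axis), with a star where camera at the preset correlation called the list and colours limited to 1 on either side of 0. The receptor target list stands at 0.85 after dexamethasone and at 0.20 when dexamethasone plus AICAR is set against AICAR, and the macrophage list stands at -3.92 after both agents.

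The combination was then set against vehicle. Many of the deepest falls were in genes of resident liver macrophages. Cd5l changed by -6.68 ± 0.07 (adjusted p = 1.24e-09), to a mean of 3.12, below the lower quartile of every array, so the size of its fall is uncertain here and in the comparisons below. The chemokine gene Ccl6 changed by -5.64 ± 0.08, the Kupffer cell lectin gene Clec4f by -5.13 ± 0.09, the complement gene C1qa by -4.77 ± 0.09, C1qb by -4.58 ± 0.22 and Aif1 by -4.42 ± 0.10. The mean of Aif1 after both agents (3.74) was below 3.84, so the size of its fall is also uncertain. Among the largest rises were those of Ces2c (5.60 ± 0.14), Lcn2 (4.49 ± 0.11), Sqor (4.28 ± 0.15), A2m (4.27 ± 0.09), the fatty acid-binding protein gene Fabp4 (3.38 ± 0.12) and Isg15 (3.38 ± 0.09). In all, 8350 probe sets were called, 4130 higher and 4220 lower, with 964 at 2-fold or more.

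Of 11 macrophage markers 10 fell after the combination and Lyz2 rose by 0.58 (10 and 1 when adjusted over the list alone), with a median of -3.92 (list adjusted p = 3.21e-09, and adjusted p = 0.276 with an estimated correlation). That median is the value of Cd163, whose mean after both agents (3.43) was below 3.84, so its size is uncertain. Lymphocyte markers fell in 11 of 15 cases (11 when adjusted over the list alone), including the pan-leukocyte gene Ptprc (-2.48 ± 0.10), with list adjusted p = 2.25e-04 and adjusted p = 0.392 with an estimated correlation. Sinusoidal endothelial markers fell in 5 of 11 cases (6 when adjusted over the list alone, with 1 rise), with a median of -0.20 and no call for the list (adjusted p = 0.052). Proliferation genes fell in 18 of 23 cases and rose in 1 (21 and 1 when adjusted over the list alone). Ccna2 changed by -3.85 ± 0.14, to a mean of 2.08 that leaves the size of its fall uncertain, and Cdk1 by -3.22 ± 0.16 (list adjusted p = 4.44e-08, and adjusted p = 0.0953 with an estimated correlation).

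Ribosomal protein genes rose in 17 of 18 cases (17 when adjusted over the list alone), including Rps16 (0.94 ± 0.07) and Rpl4 (0.90 ± 0.07), in arrays whose 5S ribosomal RNA control was 1.22 above vehicle (adjusted p = 3.92e-10 for the list, and adjusted p = 0.392 with an estimated correlation). Heat shock protein genes rose in 8 of 12 cases (8 when adjusted over the list alone). Cryab changed by 2.05 ± 0.10, Hspb1 by 1.28 ± 0.08 and Hsph1 by 0.90 ± 0.08 (list adjusted p = 2.02e-05, and adjusted p = 0.392 with an estimated correlation). Respiratory chain genes rose in 12 of 25 cases and fell in 1 (13 and 1 when adjusted over the list alone). Ndufb8 changed by 0.81 ± 0.09 (list adjusted p = 0.00124, and adjusted p = 0.534 with an estimated correlation). Endoplasmic reticulum stress and amino acid response genes rose in 11 of 24 cases and fell in 4 (12 and 4 when adjusted over the list alone). Creld2 changed by 1.71 ± 0.07 and Sesn2 by -0.85 ± 0.08 (list adjusted p = 0.0259, and adjusted p = 0.392 with an estimated correlation).

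Among lists of metabolism, those of bile acids, fatty acid and triglyceride synthesis and NRF2 were called lower. Cholesterol synthesis (9 of 21 higher, 3 lower; median 0.12, adjusted p = 0.161) and fatty acid oxidation (10 of 21 higher, 7 lower; median 0.17, adjusted p = 0.354) were not called. Bile acid synthesis and transport genes fell in 10 of 18 cases and rose in 2 (10 and 2 when adjusted over the list alone), with Nr0b2, which encodes the repressor SHP, at -4.07 ± 0.09 and the sterol exporter gene Abcg5 at -2.56 ± 0.13. The genes of that list that rose were the synthetic enzymes Cyp8b1 (1.61 ± 0.08) and Cyp7a1 (1.22 ± 0.07; adjusted p = 0.0033 for the list, and adjusted p = 0.392 with an estimated correlation). Fatty acid and triglyceride synthesis genes fell in 11 of 21 cases and rose in 5 (11 and 5 when adjusted over the list alone), with the desaturase genes Fads1 at -2.20 ± 0.07 and Scd at -2.09 ± 0.07 (list adjusted p = 0.024, and adjusted p = 0.392 with an estimated correlation). NRF2 genes fell in 10 of 17 cases and rose in 3 (11 and 4 when adjusted over the list alone). Akr7a3 changed by -1.71 ± 0.09 and Nqo1, which rose, by 1.98 ± 0.07 (list adjusted p = 0.0186, and adjusted p = 0.392 with an estimated correlation).

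Panel genes differed in where the combination left them. Fkbp5 stood 2.25 ± 0.10 above vehicle, Tsc22d3 1.44 ± 0.10, Per1 0.76 ± 0.12, Igfbp1 0.55 ± 0.07 and Ppargc1a 0.51 ± 0.10. Tat did not differ from vehicle by the test (0.11 ± 0.07, adjusted p = 0.3). Pck1 was lower than vehicle by -0.68 ± 0.07 (adjusted p = 1.47e-04), Srebf1 by -0.47 ± 0.08, Sgk1 by -2.04 ± 0.07 and Nr3c1 by -1.26 ± 0.09 (adjusted p = 1.67e-05).

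**Figure D2:**
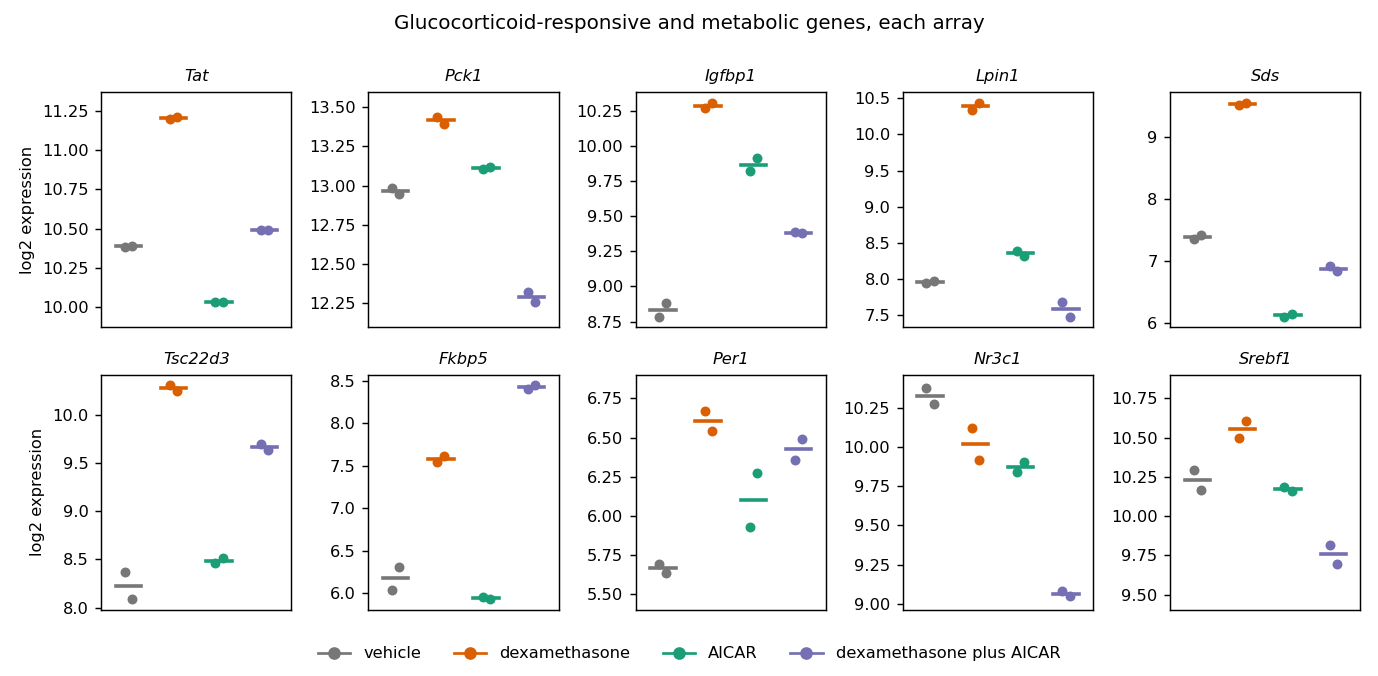
Log2 expression of 10 genes on each of the 8 arrays (points), by group, with the group mean as a bar; vertical axes differ between genes and do not start at 0. Pck1 is higher than vehicle by 0.45 after dexamethasone and lower by -0.68 after both agents, whereas Fkbp5 is highest after both agents.

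The dexamethasone effect in the presence of AICAR was read from the combination against AICAR alone. A2m rose by 6.15 ± 0.09 (71.2-fold) and Ces2c by 5.10 ± 0.14, with further rises of Rbp7 (3.58 ± 0.20), Fabp4 (3.33 ± 0.12) and the translation repressor gene Eif4ebp3 (3.07 ± 0.07). The largest falls were in Cd5l (-6.96 ± 0.07), Ccl6 (-5.77 ± 0.08), C1qb (-5.42 ± 0.22) and C1qa (-5.17 ± 0.09). Fkbp5 rose by 2.48 ± 0.10, Tsc22d3 by 1.18 ± 0.10 and Tat by 0.46 ± 0.07. Pck1 fell by 0.83 ± 0.07, Igfbp1 by 0.48 ± 0.07, Srebf1 by 0.42 ± 0.08, Nr3c1 by 0.81 ± 0.09 and Sgk1 by 0.97 ± 0.07. Per1 did not pass (0.32 ± 0.12, adjusted p = 0.0675) but did without AICAR replicate 2 (0.50, adjusted p = 0.0134). Ppargc1a (0.36 ± 0.10, adjusted p = 0.0203) lost its call without AICAR replicate 1 (adjusted p = 0.114) or either combination array (adjusted p = 0.0922 and 0.0768).

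In this setting 9563 probe sets were called, 4935 higher and 4628 lower, with 1040 at 2-fold or more. Of the receptor targets 12 of 26 rose and 9 fell (13 and 10 when adjusted over the list alone), and the list was not called (median 0.20, adjusted p = 0.67). Macrophage markers fell in 10 of 11 cases with Lyz2 higher (10 and 1 when adjusted over the list alone; median -3.97, adjusted p = 6.44e-09, and adjusted p = 0.276 with an estimated correlation). Proliferation genes fell in 19 of 23 cases and rose in 2 (20 and 3 when adjusted over the list alone). Ccnb1 changed by -2.29 ± 0.12 (list adjusted p = 1.48e-06, and adjusted p = 0.143 with an estimated correlation). Ribosomal protein genes rose in 17 of 18 cases (17 when adjusted over the list alone; adjusted p = 6.11e-08, and adjusted p = 0.353 with an estimated correlation). Heat shock genes rose in 10 of 12 (11 when adjusted over the list alone). Hsph1 changed by 1.55 ± 0.08 (list adjusted p = 9.61e-06, and adjusted p = 0.327 with an estimated correlation). Respiratory chain genes rose in 11 of 25 cases (13 when adjusted over the list alone; adjusted p = 0.0014, and adjusted p = 0.538 with an estimated correlation).

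Further lists fell against AICAR alone. Fatty acid and triglyceride synthesis genes fell in 13 of 21 cases and rose in 2 (15 and 4 when adjusted over the list alone). Scd changed by -2.21 ± 0.07 and Thrsp by -1.81 ± 0.08 (list adjusted p = 3.6e-04, and adjusted p = 0.327 with an estimated correlation). Bile acid genes fell in 12 of 18 cases and rose in 1 (13 and 1 when adjusted over the list alone), with the bile salt export pump gene Abcb11 at -0.94 ± 0.07 (list adjusted p = 7.64e-05, and adjusted p = 0.327 with an estimated correlation). Cholesterol genes fell in 13 of 21 cases and rose in 4 (14 and 4 when adjusted over the list alone; adjusted p = 0.00711, and adjusted p = 0.538 with an estimated correlation). NRF2 genes fell in 10 of 17 cases and rose in 3 (10 and 3 when adjusted over the list alone). Hmox1 changed by -1.58 ± 0.10 (list adjusted p = 0.00295, and adjusted p = 0.341 with an estimated correlation). Genes of insulin, IGF and growth hormone signalling fell in 12 of 21 cases and rose in 3 (12 and 3 when adjusted over the list alone). Egfr changed by -1.61 ± 0.07 and Ghr by -0.73 ± 0.07 (list adjusted p = 0.0105, and adjusted p = 0.473 with an estimated correlation). Lymphocyte markers fell in 8 of 15 cases (9 when adjusted over the list alone; adjusted p = 0.00318, and adjusted p = 0.341 with an estimated correlation). Endothelial markers fell in 5 of 11 cases with 1 rise (7 and 1 when adjusted over the list alone; adjusted p = 0.0333, and adjusted p = 0.341 with an estimated correlation). Cytokine and NF-kB genes fell in 12 of 25 cases and rose in 5 (13 and 5 when adjusted over the list alone; adjusted p = 0.0333, and adjusted p = 0.384 with an estimated correlation), a call that ended under cyclic loess.

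The AICAR effect in the presence of dexamethasone was read from the combination against dexamethasone alone. Lipin 1 and serine dehydratase transcripts, raised by dexamethasone, were lower with AICAR added: Lpin1 fell by 2.80 ± 0.09 and Sds by 2.66 ± 0.07. Pck1 fell by 1.13 ± 0.07 (2.18-fold lower, adjusted p = 1.52e-05), Igfbp1 by 0.90 ± 0.07, Srebf1 by 0.80 ± 0.08, Tat by 0.71 ± 0.07, Tsc22d3 by 0.61 ± 0.10, Sgk1 by 0.55 ± 0.07 and Nr3c1 by 0.95 ± 0.09. Fkbp5 went the other way and rose by 0.84 ± 0.10, while Per1 (-0.18 ± 0.12, adjusted p = 0.349) and Ppargc1a (-0.07 ± 0.10, adjusted p = 0.701) did not pass. Among the largest other changes were rises of Sqor (4.13 ± 0.15), Lcn2 (3.64 ± 0.11), Fabp4 (3.46 ± 0.12) and the neuropeptide gene Npy (2.55 ± 0.07), and falls of Cd5l (-4.81 ± 0.07), Nr0b2 (-4.30 ± 0.09), Clec4f (-4.18 ± 0.09) and the scavenger receptor gene Cd163 (-3.52 ± 0.10).

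Of 26 receptor targets 18 fell and 4 rose when AICAR was added to dexamethasone (19 and 4 when adjusted over the list alone; median -0.71, adjusted p = 6.29e-09, and adjusted p = 0.275 with an estimated correlation). Cholesterol synthesis and uptake genes rose in 17 of 21 cases and fell in 2 (18 and 2 when adjusted over the list alone). Idi1 changed by 2.04 ± 0.08 and Msmo1 by 1.96 ± 0.07 (list adjusted p = 6.29e-09, and adjusted p = 0.29 with an estimated correlation). Amino acid catabolism genes fell in 15 of 24 cases and rose in 2 (16 and 3 when adjusted over the list alone). Bckdhb changed by -2.20 ± 0.07 (list adjusted p = 5.37e-07, and adjusted p = 0.29 with an estimated correlation). Gluconeogenic genes fell in 8 of 18 cases and rose in 1 (8 and 1 when adjusted over the list alone). Pygl changed by -1.38 ± 0.07 and Fbp1 by -1.30 ± 0.07 (list adjusted p = 4.06e-04, and adjusted p = 0.29 with an estimated correlation). Periportal markers fell in 6 of 11 cases (6 when adjusted over the list alone; adjusted p = 1.71e-04, and adjusted p = 0.275 with an estimated correlation). Insulin, IGF and growth hormone signalling genes fell in 9 of 21 cases with no rise (10 and 1 when adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.371 with an estimated correlation).

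Fatty acid and triglyceride synthesis genes fell in 8 of 21 cases and rose in 5 against dexamethasone alone (12 and 5 when adjusted over the list alone). Acaca changed by -1.64 ± 0.07 (list adjusted p = 0.00107, and adjusted p = 0.305 with an estimated correlation). Bile acid genes fell in 8 of 18 cases and rose in 3 (9 and 3 when adjusted over the list alone), with Cyp8b1, which rose, at 1.64 ± 0.08 (list adjusted p = 0.0145, and adjusted p = 0.371 with an estimated correlation). Ribosomal protein genes rose in 16 of 18 cases (17 when adjusted over the list alone; adjusted p = 3.78e-07, and adjusted p = 0.371 with an estimated correlation). Heat shock genes rose in 7 of 12 (8 when adjusted over the list alone; adjusted p = 1.96e-04, and adjusted p = 0.306 with an estimated correlation). Macrophage markers fell in 9 of 11 cases and rose in 2, Lyz2 and Cd14 (9 and 2 when adjusted over the list alone; median -3.08, adjusted p = 1.18e-08, and adjusted p = 0.275 with an estimated correlation). In all, 6233 probe sets were called, 3156 higher and 3077 lower, with 548 at 2-fold or more, and the count fell to 3698 and 3823 without combination replicate 1 and 2.

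**Figure D3:**
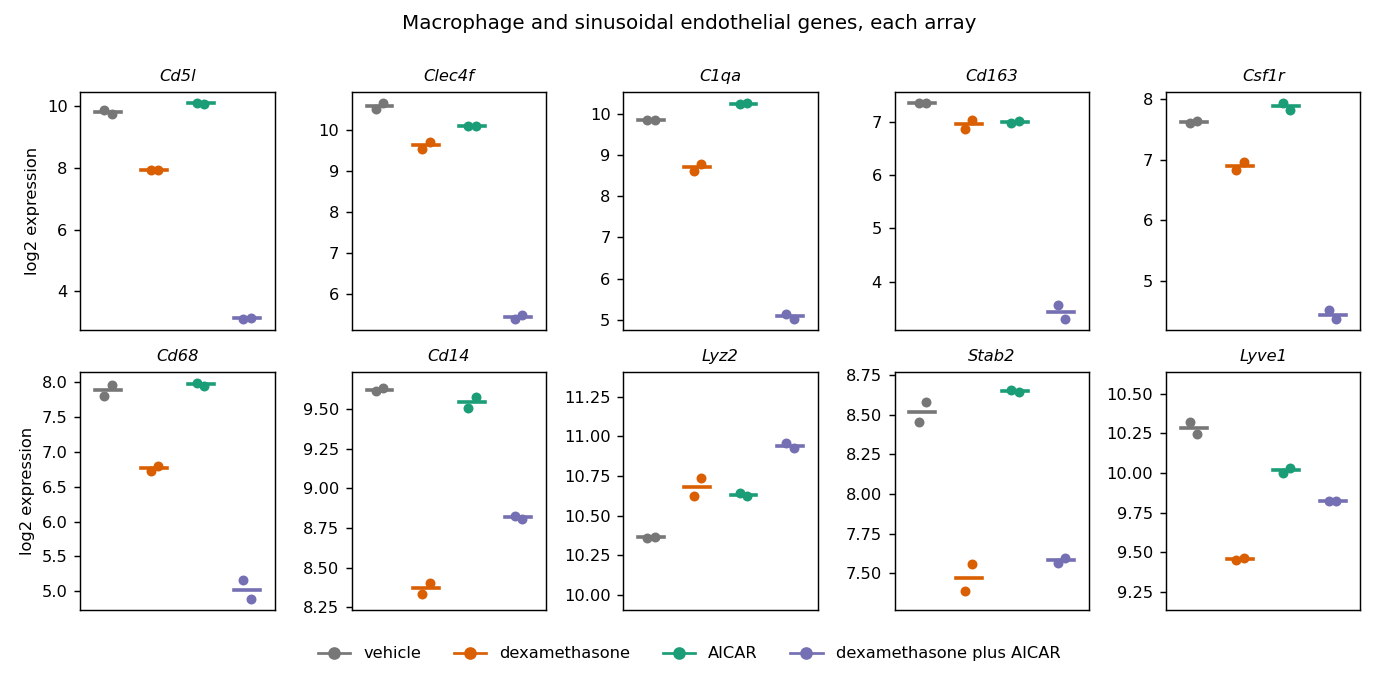
Log2 expression of 8 macrophage genes and 2 sinusoidal endothelial genes, Stab2 and Lyve1, on each of the 8 arrays (points), by group, with the group mean as a bar; vertical axes differ between genes and do not start at 0. After both agents Cd5l, Clec4f, C1qa, Cd163, Csf1r and Cd68 are lowest, Cd14 and the endothelial genes stand near or above their level after dexamethasone alone, and Lyz2 is highest.

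The interaction tested directly whether the dexamethasone effect differed with AICAR. It was negative for most receptor targets, so that dexamethasone raised them less, or lowered them, when AICAR was present. Lpin1 gave -3.20 ± 0.12, Mt2A -2.86 ± 0.10, Igfbp1 -1.94 ± 0.11 (adjusted p = 1.47e-05), the phosphatase gene Dusp1 -1.56 ± 0.10, Pck1 -1.27 ± 0.10 (adjusted p = 9.75e-05), Tsc22d3 -0.87 ± 0.14 and Srebf1 -0.74 ± 0.12. For Fkbp5 it was positive (1.08 ± 0.14, adjusted p = 0.00125), and so it was for Sgk1 (0.52 ± 0.10, adjusted p = 0.0115), whose call ended without combination replicate 2 (adjusted p = 0.0502). Ppargc1a did not pass (-0.21 ± 0.14, adjusted p = 0.356).

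Tat (-0.36 ± 0.09, adjusted p = 0.0357), Per1 (-0.61 ± 0.17, adjusted p = 0.0385) and Nr3c1 (-0.50 ± 0.13, adjusted p = 0.0283) passed the interaction test narrowly. Tat lost its call without any 1 of the 8 arrays (adjusted p from 0.0632 to 0.106). Per1 did so without any array other than AICAR replicate 1 (adjusted p from 0.0629 to 0.125). Nr3c1 did so without any other than vehicle replicate 1 and dexamethasone replicate 2 (adjusted p from 0.0628 to 0.0896).

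Of the 26 receptor targets 19 had a negative and 2 a positive interaction (19 and 3 when adjusted over the list alone), with a median of -0.61 (list adjusted p = 4.32e-08, and adjusted p = 0.246 with an estimated correlation). The sign does not give the size of a response where dexamethasone lowered a gene: the fall of Sgk1 was smaller with AICAR (-1.49 and -0.97) and that of Pdk4 larger (-1.15 and -1.64). Of the 20 targets that dexamethasone alone raised, 10 were also called higher in the presence of AICAR, 6 were called lower and 4 were not called. Their median change was 0.97 without AICAR and 0.28 with it; these 20 were picked by their rise in the first comparison, which inflates the former value and the fall from it to the latter.

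Other metabolic lists also had negative interactions. For fatty acid and triglyceride synthesis 10 of 21 genes were lower and 1 higher (11 and 1 when adjusted over the list alone). Thrsp gave -3.33 ± 0.11, Acaca -2.30 ± 0.10 and Scd -2.08 ± 0.10 (list adjusted p = 6.21e-06, and adjusted p = 0.276 with an estimated correlation). For amino acid catabolism 12 of 24 were lower and 2 higher (13 and 3 when adjusted over the list alone). Bckdhb gave -2.35 ± 0.11 and Sds -1.41 ± 0.10 (list adjusted p = 4.61e-05, and adjusted p = 0.329 with an estimated correlation). For gluconeogenesis 7 of 18 were lower and 1 higher (10 and 2 when adjusted over the list alone), with the glycogen phosphorylase gene Pygl at -1.31 ± 0.10 and Fbp1 at -1.07 ± 0.10 (list adjusted p = 0.00148, and adjusted p = 0.329 with an estimated correlation). For glycolysis 6 of 16 were lower (6 when adjusted over the list alone). Pklr gave -1.67 ± 0.10 (list adjusted p = 0.00148, and adjusted p = 0.329 with an estimated correlation). For bile acid genes 9 of 18 were lower and 2 higher (9 and 2 when adjusted over the list alone). Nr0b2 gave -4.09 ± 0.12 and Cyp7a1 -1.72 ± 0.10 (list adjusted p = 9.34e-04, and adjusted p = 0.329 with an estimated correlation). Insulin, IGF and growth hormone signalling genes were lower in 6 of 21 cases (6 and 1 when adjusted over the list alone). Irs2 gave -0.99 ± 0.13 (list adjusted p = 0.00572, and adjusted p = 0.426 with an estimated correlation). Periportal markers were lower in 4 of 11 cases (4 when adjusted over the list alone; adjusted p = 0.0335, and adjusted p = 0.337 with an estimated correlation).

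Macrophage markers had the most negative interaction of the lists, with 9 of 11 lower and 1, Cd14, higher (9 and 1 when adjusted over the list alone) and a median of -3.17. Values were -5.10 ± 0.10 for Cd5l, -4.01 ± 0.12 for C1qa and -2.71 ± 0.12 for the growth factor receptor gene Csf1r (list adjusted p = 1.47e-09, and adjusted p = 0.246 with an estimated correlation). Acute phase genes were lower in 8 of 19 cases and higher in 4 (10 and 4 when adjusted over the list alone). Lbp gave -2.68 ± 0.10 and Hamp 2.25 ± 0.13 (list adjusted p = 0.0335, and adjusted p = 0.426 with an estimated correlation). Heat shock genes were higher in 6 of 12 cases (9 when adjusted over the list alone). Hsph1 gave 1.90 ± 0.11 and Hspa1a 0.89 ± 0.13 (list adjusted p = 9.34e-04, and adjusted p = 0.329 with an estimated correlation). Ribosomal protein genes were higher in 3 of 18 cases, Rpl18, Rpl14 and Rps6 (10 when adjusted over the list alone; adjusted p = 0.00304, and adjusted p = 0.544 with an estimated correlation). Each of the 3 lost its call without either combination array (adjusted p from 0.0694 to 0.15), as did Rpl14 and Rps6 under cyclic loess (adjusted p = 0.0703 and 0.102). Among the largest positive values were also those of Npy (2.88 ± 0.10), Fabp4 (3.40 ± 0.17), the mitochondrial isomerase gene Eci1 (2.55 ± 0.13), the cyclin gene Ccnd1 (3.28 ± 0.12) and the chemokine gene Cxcl1 (2.48 ± 0.19).

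Class I and II histocompatibility genes of the RT1 complex were among the largest changes. RT1-N2 stood at 7.05 ± 0.14 (SD, n = 2) in vehicle, 3.68 ± 0.23 after dexamethasone, 4.41 ± 0.08 after AICAR and 8.72 ± 0.03 after both, an interaction of 7.68 ± 0.16. RT1-CE12 (4.63 ± 0.17) and RT1-A (2.94 ± 0.28) had positive interactions and RT1-Bb a negative one (-4.03 ± 0.19), and the other probe set of RT1-Bb was called in the opposite direction. These genes are polymorphic and closely related in sequence, so a probe set can read several of them or miss an allele, and their values are uncertain.

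By the interaction test 4858 of 31042 probe sets were called, 2679 higher and 2179 lower, with 767 at 2-fold or more. Of called probe sets 55.1% were higher as deposited, but 47.4% with cyclic loess and 48.7% with centring. The count fell to 3130 without AICAR replicate 1 and to 2910 and 3041 without combination replicate 1 and 2. The remaining lists, of pericentral hepatocyte, general hepatocyte, cholangiocyte and neutrophil markers, immediate early, circadian clock, p53 target and purine metabolism genes, drug and steroid metabolism, and the AMPK, p38 MAPK and receptor components, were not called by camera in any of the 6 comparisons, with 0.059 as the lowest adjusted p.

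Across all 31042 probe sets the dexamethasone effect without AICAR and that with AICAR, which share no array, correlated at r = 0.487 (Spearman's rho = 0.349), across probe sets that are not independent replicates. Of 3649 probe sets called in both, 3134 changed the same way, with 1486 higher in both (428 expected from independent lists) and 1648 lower in both (452 expected). The other 515 changed in opposite ways. The AICAR effect without and with dexamethasone correlated at r = 0.107 (rho = 0.0799), and 1691 probe sets were called in both. Of these, 440 were higher in both (172 expected from independent lists) and 634 lower in both (230 expected). The other 617 changed in opposite ways, 263 from higher to lower (168 expected) and 354 from lower to higher (236 expected).

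**Figure D4:**
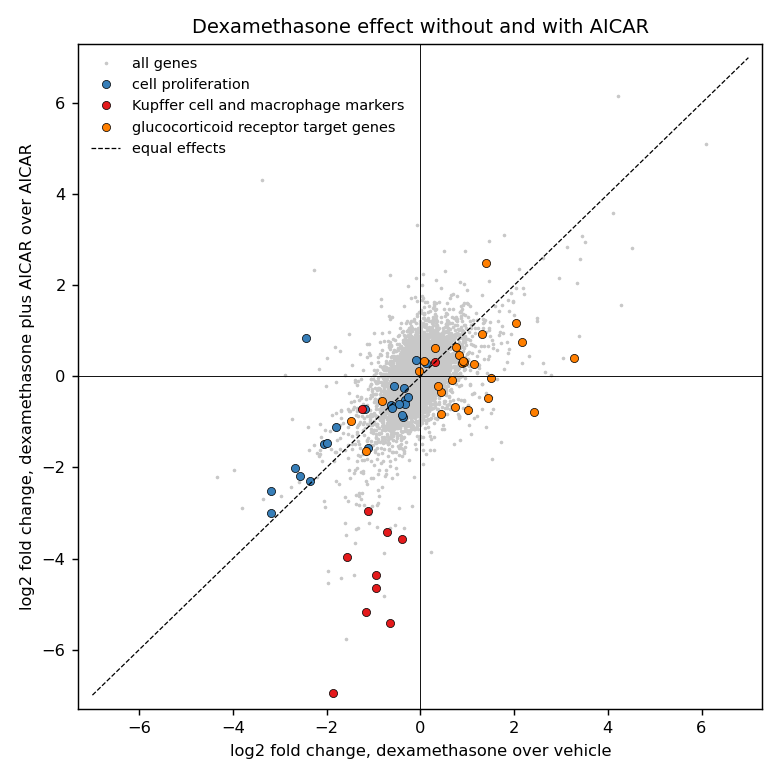
Log2 fold change of each gene after dexamethasone against vehicle (horizontal axis) and after dexamethasone plus AICAR against AICAR (vertical axis), with 3 gene lists in colour and a dashed line of equal effects. Proliferation genes lie near the line, with Ccnd1 as an exception at -2.43 on the horizontal axis, receptor targets mostly lie below it, and most macrophage markers lie far below it, down to Cd5l at -6.96.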

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

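Of the tests in this part, the one of spread at RT1 probe sets was written before its result was seen, and the other tests were chosen after the results were seen. The 95% intervals here came from resampling the genes of a list, or the RT1 probe sets, with the 8 arrays held fixed. They hold no spread between arrays, and the genes of a list need not be independent. What drew attention here was a dexamethasone effect that differed with AICAR by the interaction test, and a signal in a control probe set outside the comparisons. By the interaction test 4858 probe sets differed.

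The macrophage list had a median of -3.92 after both agents and -0.96 after dexamethasone, and was not called after AICAR (4 rose, 1 fell, median 0.27, adjusted p = 0.155); the interaction was -3.17 for the median of the list, -5.10 for Cd5l, -4.77 for C1qb, -4.18 for Ccl6, -4.01 for C1qa, -3.69 for Clec4f and -3.41 for C1qc. A lower share of every cell type other than hepatocytes as the whole cause is argued against by the marker lists. The macrophage list fell by 3.72 more than the sinusoidal endothelial list after both agents (difference -3.72, 95% interval -4.62 to -2.41, medians -3.92 and -0.20). The former median is the value of Cd163, whose mean after both agents (3.43) was below 3.84, so the size of the difference is uncertain. Further genes of both cell types parted less (medians -1.31 and -0.49, SD 0.81 and 0.58), and lymphocyte markers were also called lower (median -0.45). A smaller fall of several cell types together stays open. Fewer macrophages may be a candidate explanation: of 22 further macrophage and myeloid genes, 20 were called lower (median -1.31), although Lyz2 rose by 0.58. Dexamethasone alone already lowered 19 of the 22 (median -0.80), and their interaction had a median of -0.46 with 11 of 22 lower and 0 higher (adjusted p = 7.64e-09, and adjusted p = 0.0734 with an estimated correlation). Macrophages that stayed but held less of the marker transcripts cannot be told apart from this, because the further genes fell less than the markers (difference 2.61, 95% interval 1.52 to 3.66) but many of them are also expressed by other cells.

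RT1 genes did not all change alike. Some class II genes, such as RT1-Da, were lower after dexamethasone (-1.59), higher after AICAR (1.21) and lowest after both (-2.27). RT1-DMa was instead higher after each (2.17, 0.92 and 1.22). RT1-Bb moved the same ways as RT1-Da (-0.78, 0.91 and -3.91, interaction -4.03), but its other probe set fell each time (-2.04, -1.43 and -0.66). RT1-N2 (-3.37, -2.64 and 1.68) and RT1-CE12 (-2.28, -1.96 and 0.38) were lower after either agent but not after both. Their interactions were 7.68 and 4.63. RT1-A, with an interaction of 2.94, was called lower after dexamethasone alone (-2.90), where its SD was 0.53, but not after AICAR (-0.26) or both (-0.22). Animals of different RT1 haplotype could give such values. The test of this covered only genes with several probe sets. It could not decide for RT1-N2, RT1-CE12 and RT1-A, which have 1 probe set each. Of 6 RT1 genes with several probe sets, 1 (16.7%) had probe sets called in opposite directions against vehicle. Of 4520 other genes 99 did (2.19%, Fisher's exact p = 0.126), which left haplotype open for those 6 genes too. If both arrays of a group carried RNA of the same animal or pool, RT1 probe sets would spread no more within groups than others. The ratio of their spread to that of probe sets of like level was 1.43 (95% interval 0.959 to 1.63, 31 probe sets), which leaves this open as well. An effect of the treatments on these genes was not tested apart from haplotype.

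Glucocorticoid receptor targets mostly had a negative interaction (19 of 26, with 2 positive), at -0.61 for the list median (adjusted p = 4.32e-08, and adjusted p = 0.246 with an estimated correlation), -1.94 for Igfbp1, -1.27 for Pck1, -0.87 for Tsc22d3, -0.61 for Per1 and -0.36 for Tat, but 1.08 for Fkbp5 and 0.52 for Sgk1, which dexamethasone lowered (-1.49, and -0.97 with AICAR). Compressed fold changes on the combination arrays would lower the SD of the dexamethasone effect over all probe sets. It was 1.26 times as large with AICAR as without (0.436 and 0.345). This SD also holds effects particular to both agents, such as the macrophage falls, so it cannot exclude weaker responses of other genes. A weakening of every dexamethasone effect alike is argued against for proliferation genes alone. They kept a larger part of their mean effect than receptor targets (0.783 and 0.0871, difference 0.696, 95% interval 0.291 to 1.22). Among other lists that dexamethasone raised, amino acid catabolism, gluconeogenesis and glycolysis had negative interactions and ribosomal proteins a positive one. The first of these shares Tat, Tdo2 and Sds with the receptor targets, and gluconeogenesis shares Pck1, so these results are not separate from those of the targets. A lower share of hepatocytes as the whole cause would raise the markers of all other cell types alike. From dexamethasone to both agents macrophage and endothelial markers moved apart (medians -3.08 and 0.11, difference -3.19, 95% interval -4.06 to -1.85). The test cannot decide, because macrophage markers had a fall of their own, flagged above, that would part the lists at any share of hepatocytes. The further macrophage and endothelial lists did not part (medians -0.32 and -0.12, SD 0.55 and 0.51) and did not rise either. These values do not favour a lower share of hepatocytes, but it stays open. An earlier test of it, on markers below a level of 13, decided nothing. The limit left out 9 of 11 hepatocyte markers, so most of those tested were pericentral markers. The 10 hepatocyte and pericentral markers stood above the targets by 0.67 (95% interval 0.02 to 1.19), which met the bound set for the test. But they went both ways with an SD of 0.80, a condition added after that result. An action of AICAR on the receptor or its targets and the lower Nr3c1 transcript (interaction -0.50) stay open and untested, and protein phosphorylation was not measured here.

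Other interactions are given as values without a weighing. List medians were -0.30 for fatty acid and triglyceride synthesis, -0.32 for amino acid catabolism and the urea cycle, -0.47 for bile acid synthesis and transport, -0.30 for gluconeogenesis, -0.26 for glycolysis, -0.14 for insulin, IGF and growth hormone signalling (-0.21 with cyclic loess), -0.029 for periportal markers (-0.14 with cyclic loess, -0.062 with centring), -0.27 for acute phase proteins, 0.38 for heat shock proteins and 0.27 for ribosomal proteins (0.18 with cyclic loess). Single genes gave -4.09 (Nr0b2), -0.74 (Srebf1), 3.40 (Fabp4), 3.28 (Ccnd1), 2.88 (Npy), 2.55 (Eci1) and 2.48 (Cxcl1). The 5S ribosomal RNA control, which no comparison used, stood above vehicle by 0.30 after dexamethasone, 0.42 after AICAR and 1.22 after both, on the log2 scale.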

How the results depend on the processing

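The alternatives for the correlation of the AICAR effect and the 2 rescalings (cyclic loess, centring) of the gene lists were chosen after values were seen; the others were planned. The more frequent direction among called probe sets turned under a rescaling in all 6 comparisons. A 2-fold minimum left 605 probe sets for dexamethasone against vehicle, 169 for AICAR, 964 for both, 1040 for both against AICAR, 548 for both against dexamethasone and 767 for the interaction. Gene means, with 14216 genes tested in place of 31042 probe sets, gave 3665, 2606, 5320, 5789 and 4052 for these comparisons other than the interaction. For AICAR against vehicle, a trended and robust prior gave 6048 and a fit of only the compared groups, with fewer arrays, 2345. Estimated correlations left 1 list for dexamethasone and 0 in each of the other comparisons, where fry called 20 to 26. With only probe sets above the median level, 14, 9, 8, 11, 11 and 14 lists were called in place of 15, 9, 10, 13, 11 and 12. The correlation of the dexamethasone effect was 0.519 above the median level and 0.537 over gene means, and that of the AICAR effect 0.132 and 0.12; the cause was not tested.

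Leaving out 1 array, so that a lone array is assumed to vary like the other groups, gave 3738 (without vehicle replicate 2) to 5303 probe sets for dexamethasone, 5677 to 8386 for both, and 6510 to 9596 for both against AICAR. For AICAR it gave 1447 to 3819, with 1447 and 1989 without AICAR replicate 1 and 2 and 1713 and 1920 without vehicle replicate 1 and 2. For both against dexamethasone it gave 3698 to 5985 (3698 and 3823 without combination replicate 1 and 2), and for the interaction 2910 to 3991 (2910 and 3041 without combination replicate 1 and 2, 3130 without AICAR replicate 1). The correlations ranged from 0.458 to 0.486 and from 0.0913 to 0.111. Of 766 results for named genes 0 reversed, 82 lost their call without at least 1 array, 15 with gene means and 13 with the replicate number as a block. Calls of named genes also ended in 11 results under cyclic loess, 6 under centring and 6 under the trended and robust prior. The count of reversals covers only the 756 results that were called. Among uncalled results the sign changed 1 time under cyclic loess, 2 times with gene means and 2 times without 1 array. Arrays with the same replicate number showed no strong shared shift (r of replicate differences between groups -0.04 to 0.16). This cannot exclude a pairing, which the labels do not state. List counts without 1 array were 15, 8 to 10, 10 to 11, 11 to 13 (11 without AICAR replicate 1), 10 to 12 and 10 to 15 (10 without vehicle replicate 2). With cyclic loess, 2 list calls ended: fatty acid oxidation after AICAR (median -0.06) and cytokines in both against AICAR (-0.28). It took the respiratory chain in both against AICAR from a median of 0.22 to 0.14 with its call kept. With 2 arrays per group and no detection calls, small changes of dim genes are the least certain.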

Other observations

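The lists and tests in this part were chosen after the values were seen. Interferon-stimulated genes rose after dexamethasone: 19 of 26 were higher and 3 lower, with a median of 0.83 (camera adjusted p = 4.97e-12, and adjusted p = 0.0323 with an estimated correlation). The list was also called higher after AICAR (9 rose, 1 fell; median 0.15, adjusted p = 0.00379, and adjusted p = 0.248 with an estimated correlation) and after both (13 rose, 5 fell; median 0.38, adjusted p = 0.00448, and adjusted p = 0.265 with an estimated correlation). After dexamethasone Mx2 rose by 2.03, Usp18 by 1.98 and Ifit3 by 1.86, whereas Gbp2 (-1.33), Psmb9 (-1.32) and Psmb8 (-0.95) fell. The interaction was negative for 13 of the 26 and positive for 0 (median -0.39, adjusted p = 3.76e-08, and adjusted p = 0.0734 with an estimated correlation), with Oas1b at -2.56 and Mx1 at -1.79. Of 9 genes of MHC class II presentation, 6 are RT1 genes, whose values may reflect haplotype as well as treatment, a question left open above. A second RT1-Bb probe set changed by -1.43 after AICAR. Of the 9, 6 fell and 1 rose after dexamethasone (median -0.78, adjusted p = 0.0432, and adjusted p = 0.28 with an estimated correlation), 8 rose after AICAR (median 0.91, adjusted p = 1.47e-08, and adjusted p = 0.248 with an estimated correlation) and 7 fell after both agents (median -1.91, adjusted p = 8.06e-05, and adjusted p = 0.265 with an estimated correlation). Macrophage markers had medians of the same signs (-0.96 after dexamethasone, 0.27 after AICAR with no call, and -3.92 after both). Cd74, the invariant chain gene, changed by -1.60 after dexamethasone, 0.99 after AICAR and -2.24 after both.

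On a list of 17 peroxisomal and other fatty acid genes, among them genes of the Cyp4a family, 10 had a positive and 4 a negative interaction (median 0.39, adjusted p = 0.0125, and adjusted p = 0.261 with an estimated correlation). Cyp4a3 gave 2.45 and Acox2 2.00, whereas Acox3 gave -1.34 and Cyp4a8 -1.26. Of 12 lipid droplet and fatty acid uptake genes, 7 rose and 2 fell after both agents (median 0.54, adjusted p = 0.0183, and adjusted p = 0.269 with an estimated correlation), with Lpl at 2.29, Cidea at 2.26 and Cd36 at -1.20. Of 15 further sinusoidal endothelial genes, 8 fell after both agents (median -0.49, adjusted p = 0.00273, and adjusted p = 0.269 with an estimated correlation), beside 20 of 22 further macrophage and myeloid genes (adjusted p = 7.56e-12, and adjusted p = 0.0494 with an estimated correlation).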
